A study of Homo sapiens with 18 samples.

How the data were processed

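Poly-A RNA was sequenced in 18 libraries from 3 human non-small cell lung cancer lines, SNU2535, NCI-H3122 and NCI-H2228, per the labels. Per the labels' protocols, cells in dishes received DMSO or 3 µM TRI-611 for 3 h, and the libraries were built with a kit that adds unique molecular identifiers. Each line has 3 DMSO and 3 TRI-611 libraries. The labels also give a batch, numbered 1 to 3, which equals the replicate number in every group. They do not say that the 3 libraries of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

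The authors deposited 1 table of TPM values (transcript abundances scaled to a fixed sum) for 57500 genes, and TPM summed to 1000000 in each library. The submitters' processing notes name fastp 0.23.1, STAR 2.5.2b, featureCounts, Subread 1.5.2, DESeq2 and the genome build GRCh38. The annotation, the strand setting, the treatment of the molecular identifiers and the way TPM was derived are not given in the sources used here. Without a stated strand setting, reads of a gene and of an overlapping antisense gene cannot be told apart. The table pairs Ensembl gene IDs with names, except for 485 genes without a name. Of the IDs, 56898 were found in GENCODE release 29, which supplied gene types and GRCh38 coordinates. TPM holds no read totals, so the depth of the libraries is unknown. A rough measure of relative reads per base, taken from the smallest values of genes of low TPM, ran from 0.815 to 1.297 times the typical library, and no interval for counting error could be given.

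The TPM values were taken as deposited and transformed to log2(TPM + 1). A fold change on this scale understates the change of genes of low TPM. Within each line, genes with a TPM of 1 or more in at least 3 of the 6 libraries were tested with limma 3.58.1 in R 4.3.3 (empirical Bayes with trend and robust settings). The test was two-sided, and a gene was called at an adjusted p under 0.05 (Benjamini-Hochberg) with no minimum change. Values written with SE are log2 changes with limma's standard error. Differences in response between lines were tested as interaction contrasts on the 12 libraries of each pair, over genes that passed the filter in both. Overlaps of calls were tested with Fisher's exact test (one-sided) in each direction. The DMSO libraries of the lines were compared with limma over the 9 libraries.

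A total of 36 gene lists was fixed, and lists with 5 or more tested members were tested in each line with limma's camera at a preset correlation of 0.01, adjusted over the lists of the line. An estimated correlation and fry were alternatives. The design, the lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule named ALK and EML4, the 10 genes of a published MAPK pathway output signature, and per line the 7 largest rises and 7 largest falls among called genes whose groups did not overlap. It also named up to 3 called members per list and line, the 6 largest mean rises and 6 largest mean falls among genes called in all 3 lines, and the 3 largest differences in each direction per pair of lines.

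The labels' batch pairs samples across groups. Deviations from the group means of samples with the same number correlated weakly: r was -0.0228, 0.0437 and 0.00966 in SNU2535, -0.0865, -0.0290 and 0.0152 in NCI-H3122, and 0.101, 0.00343 and 0.0830 in NCI-H2228 for batches 1, 2 and 3 (across genes, which are not independent replicates). A fit with the replicate block had been set as an alternative before the data were examined, and its value stands beside several results where it changed a call. Each batch holds 1 library per group, so no test of 1 line within a batch was possible.

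The steps were tested on simulated data with 200 changed genes. Of genes changed 2-fold, 71.6%, 62.7% and 79.1% were recovered in SNU2535, NCI-H3122 and NCI-H2228, and 3.33%, 3.97% and 6.37% of the calls were false. For differences in response, 84%, 82% and 70% of 2-fold differences were recovered between SNU2535 and NCI-H3122, SNU2535 and NCI-H2228, and NCI-H3122 and NCI-H2228. The false shares of those calls were 7.53%, 4.49% and 3.07%. The simulation drew independent noise and changed far fewer genes than were called in SNU2535, NCI-H3122 and NCI-H2228 (28.75%, 34.05% and 11.2% of tested genes). Its recovery may therefore not hold for these data. Alternatives were other pseudocounts (0.1 and 5), other filters, the block, median-ratio scaling, quantile normalization, a fit of all 18 libraries, plain empirical Bayes, a minimum log2 change of 1 and leaving out each library. Tests on protein-coding genes only, without mitochondrially encoded genes, of lists under the 2 other scalings, and of lists for the difference between lines were added after seeing the data. Figures were drawn with matplotlib. No library was left out of the main results.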

Results

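RNA-seq profiles were collected from 6 groups of 3 libraries each: SNU2535, NCI-H3122 and NCI-H2228 cells, each treated with DMSO or with 3 µM TRI-611 for 3 h. The 3 lines are established non-small cell lung cancer lines known for EML4-ALK fusions, and the series title describes TRI-611 as a molecular glue degrader of ALK, a receptor tyrosine kinase. Between 23766 and 25921 genes lay above 0 TPM per library, and replicates correlated at r = 0.987 to 0.990 across genes. Mitochondrially encoded genes took 8.70% ± 1.18 (SD, n = 3) of TPM with DMSO and 9.13% ± 0.691 (SD, n = 3) with TRI-611 in SNU2535. The corresponding shares were 11.2% ± 1.52 and 12.5% ± 2.19 (SD, n = 3 each) in NCI-H3122, and 9.07% ± 1.23 and 10.8% ± 0.591 (SD, n = 3 each) in NCI-H2228. The highest share, 15.0%, was in TRI-611 replicate 3 of NCI-H3122.

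The first comparison asked which transcripts differ after 3 h of the degrader within each line. ALK RNA itself (ENSG00000171094, GRCh38 chromosome 2, 29192774 to 29921566) passed the test in none of the 3 lines. It measured 24.8 ± 2.11 TPM with DMSO and 21.3 ± 0.754 TPM with TRI-611 in SNU2535 (SD, n = 3 each; log2 difference -0.21, limma adjusted p = 0.0518). In NCI-H3122 it measured 16.2 ± 1.06 and 15.1 ± 0.448 TPM (SD, n = 3 each; -0.09, limma adjusted p = 0.282), and in NCI-H2228 11.0 ± 0.137 and 10.9 ± 0.150 TPM (SD, n = 3 each; -0.02, limma adjusted p = 0.868, or 0.0047 on the log2 scale without mitochondrially encoded genes). The SNU2535 value lay near the threshold: over the alternatives its adjusted p ran from 0.0109 to 0.143, and it was 0.0163 without DMSO replicate 1. EML4, the 5' partner in these fusions, stood at -0.16 in SNU2535 (limma adjusted p = 0.0406, 0.0888 with the replicate block, 0.0718 under median-ratio scaling, and 0.195 with a log2 difference of -0.09 under quantile normalization; 0.127, 0.0592 and 0.0764 without DMSO replicates 1, 2 and 3, and 0.105 and 0.103 without TRI-611 replicates 1 and 3). It stood at 0.03 in NCI-H3122 (limma adjusted p = 0.558; -0.02 under median-ratio scaling) and at -0.02 in NCI-H2228 (limma adjusted p = 0.772; 0.0029 without mitochondrially encoded genes). RNA does not report the level of ALK protein, which was not measured here.

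In SNU2535, transcripts that ERK signalling drives fell furthest after TRI-611. DUSP6, a phosphatase that switches off ERK (ENSG00000139318, GRCh38 chromosome 12, 89347232 to 89353271), went from 27.2 ± 1.73 to 0.488 ± 0.0570 TPM (SD, n = 3 each; log2 change -4.24, SE 0.0846). SPRY4, a feedback inhibitor of receptor kinase signalling (ENSG00000187678, chromosome 5, 142310427 to 142326455), went from 19.5 ± 0.965 to 0.162 ± 0.0532 TPM (SD, n = 3 each; log2 change -4.14, SE 0.0936). PHLDA1 fell from 125 ± 2.85 to 7.61 ± 0.521 TPM (SD, n = 3 each; log2 change -3.88, SE 0.0538). The transcripts of the AP-1 factor FOSL1 (-2.93), thrombomodulin THBD (-2.93), the EGFR ligand AREG (-2.80) and the ephrin receptor EPHA2 (-2.69) also fell. All 10 genes of the MAPK output list fell, over all genes and adjusted over the list alone (median log2 change -1.76). DUSP6 and SPRY4 lay below 1 TPM with TRI-611, so they passed the filter only through the DMSO libraries. Without 1 library the median of the list ran from -1.7693 to -1.6411. Against other genes the list was lower at adjusted p = 1.45e-11 in limma's camera, and at adjusted p = 0.0723 with an estimated correlation. Within batches 1, 2 and 3 its median was -1.76, -1.72 and -1.87, with all 10 members lower each time.

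Several further groups moved down in SNU2535. Of 20 tested feedback regulators of ERK, which share DUSP4, DUSP6, SPRY2 and SPRY4 with the MAPK output list, 14 fell and 2 rose (14 and 3 adjusted over the list alone, adjusted p = 1.27e-05 in limma's camera, adjusted p = 0.0723 with an estimated correlation). Without 1 library the median of these regulators ran from -1.1963 to -0.68216. Of 30 immediate early genes, 19 fell and 4 rose (20 and 6 adjusted over the list alone), among them KLF2 (-1.67) and MAFF (-1.60) downward (adjusted p = 1.27e-05 in limma's camera, adjusted p = 0.197 with an estimated correlation). MYC and ribosome biogenesis genes fell in 30 of 33 cases (31 adjusted over the list alone; median -0.53), including MYC itself (-1.57), the ribosome assembly factor RRS1 (-1.78) and the nucleolar methyltransferase NOP2 (-1.26). For that list limma's camera gave adjusted p = 1.41e-15, and adjusted p = 0.259 with an estimated correlation. Among NF-kB targets and chemokines, 7 of 16 fell and 2 rose (8 and 2 adjusted over the list alone), with the neutrophil attractant CXCL8 at -2.27 and the cytokine LIF at -1.62 (adjusted p = 0.01002 in limma's camera, adjusted p = 0.259 with an estimated correlation). Growth factor genes AREG, HBEGF (-2.53) and EREG (-2.05) were among the 4 of 8 EGFR and FGFR ligands that fell (4 adjusted over the list alone; adjusted p = 0.0288 in limma's camera, adjusted p = 0.259 with an estimated correlation).

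Targets of FOXO transcription factors, which AKT signalling restrains, rose in SNU2535. KLHL24, a ubiquitin ligase adaptor, rose from 8.11 ± 0.518 to 34.5 ± 2.10 TPM (SD, n = 3 each; log2 change 1.96, SE 0.0674), and the PI3K inhibitor gene PIK3IP1 (1.78) and the muscle atrophy ligase FBXO32 (1.53) rose too. Of 27 FOXO targets, 20 rose and 1 fell (22 and 1 adjusted over the list alone; median 0.47; adjusted p = 4.21e-13 in limma's camera, adjusted p = 0.0685 with an estimated correlation). In the BCL2 family, the pro-death genes BMF (1.56) and BCL2L11 (1.13) rose and the survival gene BCL2L1 (-0.88) fell, while 3 of 13 members rose and 8 fell (3 and 8 adjusted over the list alone). That family had a median of -0.18 and a mean of 0.04, and did not pass as a list (adjusted p = 0.449 in limma's camera). Cytosolic ribosomal protein genes rose in 37 of 82 cases and fell in 1 (48 and 1 adjusted over the list alone; median 0.11; adjusted p = 1.18e-08 in limma's camera, adjusted p = 0.406 with an estimated correlation). Of 35 replication histone genes, 10 rose and 0 fell (10 and 0 adjusted over the list alone; adjusted p = 2.63e-05 in limma's camera, adjusted p = 0.0723 with an estimated correlation). The libraries hold poly-A RNA, so these values cover only polyadenylated histone transcripts.

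Over all genes in SNU2535, 4672 of 16252 tested were called with limma, 1731 higher and 2941 lower after TRI-611. Changes of at least 2-fold numbered 95 upward and 224 downward. The groups did not overlap for 43.9% of tested genes, where chance gives 10%. Quantile normalization shifted the split to 2500 higher and 2415 lower. Of 34 lists tested, 17 were called with limma's camera (11 without DMSO replicate 2; 13 of the 17 with the replicate block), 8 upward and 9 downward, and 0 kept the call with an estimated correlation. The largest rises included short RNA genes of low TPM, such as MIR548AR, listed at 0 in each DMSO library and at 3.21 ± 1.22 TPM (SD, n = 3) with TRI-611.

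In NCI-H3122 the same comparison again gave large falls in ERK-driven genes. DUSP6 fell from 243 ± 6.59 to 11.0 ± 1.74 TPM (SD, n = 3 each, log2 change -4.36, SE 0.0955) and SPRY4 from 25.2 ± 0.812 to 0.595 ± 0.0742 TPM (SD, n = 3 each, log2 change -4.04, SE 0.0776). Here too SPRY4 passed the filter only through the DMSO libraries. FOSL1 (-3.37), the ERK phosphatase DUSP5 (-3.05), AREG (-2.97) and the growth-induced zinc finger factor EGR1 (-2.63) also fell. In the MAPK output list 9 of 10 genes fell (10 adjusted over the list alone; median -1.29; adjusted p = 3.75e-12 in limma's camera, adjusted p = 0.190 with an estimated correlation). The remaining gene, ETV4, stood at -0.27 (limma adjusted p = 0.0603, 0.0355 with the replicate block and 0.00694 without TRI-611 replicate 1). The list's median within batches 1, 2 and 3 was -1.32, -1.27 and -1.33, with all 10 members lower each time. Immediate early genes fell in 23 of 31 cases and rose in 3 (24 and 3 adjusted over the list alone; adjusted p = 6.35e-12 in limma's camera, adjusted p = 0.190 with an estimated correlation). Of 9 EGFR and FGFR ligands 7 fell and 1 rose (7 and 1 adjusted over the list alone; adjusted p = 5.66e-06 in limma's camera, adjusted p = 0.190 with an estimated correlation).

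Genes of the G2 and M phases of the cell cycle rose in NCI-H3122. All 27 tested members were called higher, over all genes and adjusted over the list alone, with a median log2 change of 0.53 (adjusted p = 1.01e-11 in limma's camera, adjusted p = 0.450 with an estimated correlation). CDC25C, a phosphatase that activates CDK1 at mitosis, rose from 11.9 ± 0.654 to 30.8 ± 0.907 TPM (SD, n = 3 each; log2 change 1.301, SE 0.0553), and the mitotic kinesin KIF20A rose from 84.4 ± 0.917 to 188 ± 8.44 TPM (SD, n = 3 each; log2 change 1.14, SE 0.0408). The list's median within batches 1, 2 and 3 was 0.41, 0.59 and 0.53. In SNU2535 the G2/M list was also called higher, with 8 of 27 members rising and 2 falling (8 and 2 adjusted over the list alone; median 0.10; adjusted p = 0.0279 in limma's camera, adjusted p = 0.741 with an estimated correlation). That call was lost in fry (adjusted p = 0.273) and, in limma's camera, without DMSO replicate 2 (0.0660), TRI-611 replicate 2 (0.0521) or TRI-611 replicate 3 (0.0951). The list's median in SNU2535 within batches 1, 2 and 3 was -0.0045, 0.201 and 0.0987. In NCI-H2228 it was called higher too, with 7 rising and 2 falling (10 and 3 adjusted over the list alone; median 0.10; adjusted p = 0.0368 in limma's camera, adjusted p = 0.333 with an estimated correlation), and lost with the replicate block (0.0558) and without DMSO replicate 3 (0.0806) or TRI-611 replicate 3 (0.0782). In NCI-H3122 the G1 and S phase list did not pass (adjusted p = 0.344 in limma's camera): 7 of 26 members rose and 7 fell (9 and 8 adjusted over the list alone; median -0.03), with the G1 cyclin gene CCNE1 at -0.80. The same list was called lower in SNU2535, where 2 of 27 members rose and 11 fell (2 and 11 adjusted over the list alone; adjusted p = 0.0440 in limma's camera, adjusted p = 0.741 with an estimated correlation), but not with the replicate block (0.0556) or without DMSO replicate 2 (0.0660) or TRI-611 replicate 1 (0.157). It was called lower in NCI-H2228, where 1 of 26 rose and 4 fell (1 and 6 adjusted over the list alone; adjusted p = 0.00745 in limma's camera, adjusted p = 0.204 with an estimated correlation), but not under quantile normalization (0.0746). Of 10 cell cycle inhibitor genes in NCI-H3122, 7 rose and 0 fell (7 and 1 adjusted over the list alone), including CDKN1B (0.87) and CDKN2C (0.98) (adjusted p = 0.00624 in limma's camera, adjusted p = 0.605 with an estimated correlation).

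**Figure D1:**
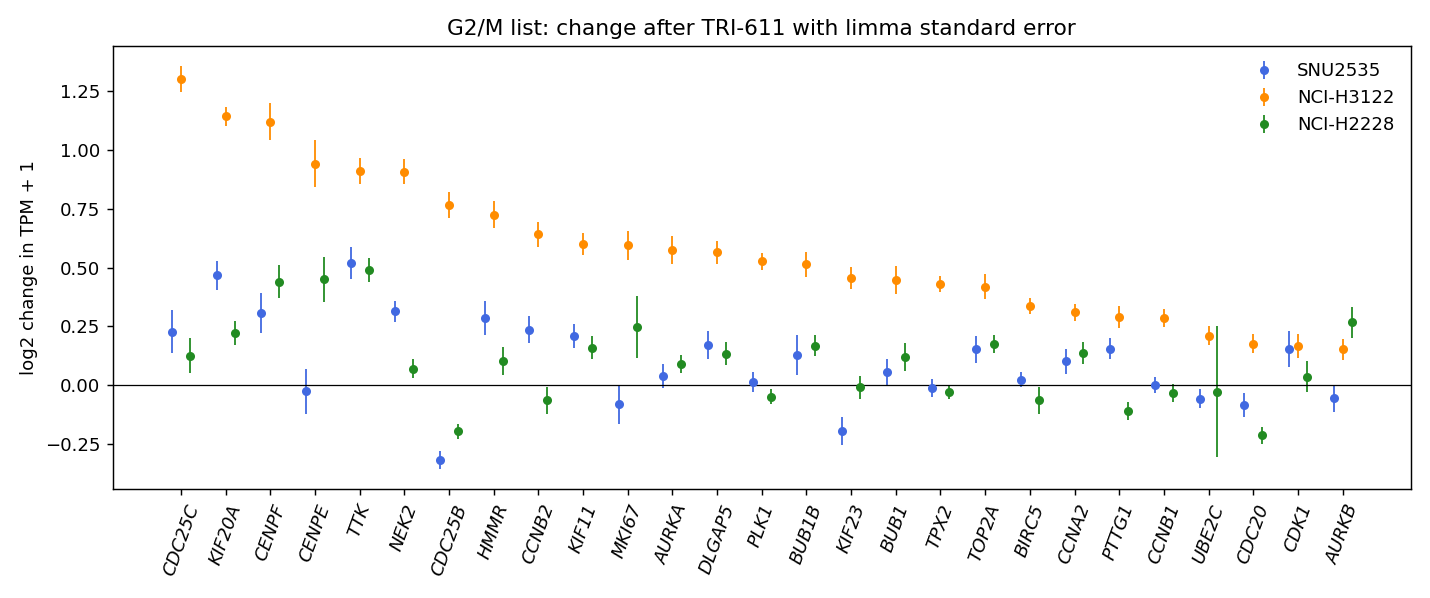
Log2 change in TPM + 1 after TRI-611 for the 27 genes of the G2/M list (horizontal axis) in the 3 lines (colours), with limma's standard error as bars. All 27 points of NCI-H3122 lie above 0, with CDC25C highest at 1.301.

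FOXO targets rose in 23 of 27 cases and fell in 2 in NCI-H3122 (23 and 2 adjusted over the list alone; median 0.79; adjusted p = 1.74e-09 in limma's camera, adjusted p = 0.332 with an estimated correlation), led by KLHL24 (2.47) and PIK3IP1 (2.09). MYC and ribosome biogenesis genes fell in 26 of 33 cases and rose in 1 (28 and 1 adjusted over the list alone; median -0.36; adjusted p = 3.36e-13 in limma's camera, adjusted p = 0.292 with an estimated correlation). In the BCL2 family 3 of 15 members rose and 6 fell (3 and 8 adjusted over the list alone), among them the pro-death genes BMF (1.88) and BBC3 (1.44) upward and the survival gene MCL1 (-0.95) downward. That list had a median of -0.16 and a mean of 0.02, and was called lower at adjusted p = 0.0369 in limma's camera, with adjusted p = 0.727 with an estimated correlation. The call was lost under median-ratio scaling (0.0748), quantile normalization (0.115) and without TRI-611 replicate 2 (0.0737). CYP1A1, a detoxifying oxygenase and a standard target of the aryl hydrocarbon receptor AhR, had the largest rise in this line, from 55.4 ± 3.99 to 323 ± 15.2 TPM (SD, n = 3 each; log2 change 2.52, SE 0.0595). ATOH8, a helix-loop-helix factor (2.31), and the Wnt receptor gene FZD2 (2.22) also rose. Of 6 AhR targets 4 rose and 0 fell (4 and 0 adjusted over the list alone; adjusted p = 0.00617 in limma's camera, adjusted p = 0.605 with an estimated correlation).

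Over all genes in NCI-H3122, limma called 5214 of 15311, 3160 higher and 2054 lower, and 189 and 147 of them changed at least 2-fold. Median-ratio scaling turned the split to 2694 higher and 2976 lower. The groups did not overlap for 48.1% of tested genes (chance gives 10%). Of 33 lists 16 were called, 5 upward and 11 downward, all 16 also with the replicate block, and 0 kept the call with an estimated correlation.

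In NCI-H2228 the ERK-driven genes fell less far. DUSP6 went from 15.2 ± 0.931 to 3.47 ± 0.275 TPM (SD, n = 3 each; log2 change -1.86, SE 0.0837) and SPRY4 from 16.9 ± 0.210 to 4.68 ± 0.369 TPM (SD, n = 3 each; log2 change -1.66, SE 0.0739). The monocyte attractant CCL2 (-1.73), the feedback inhibitor SPRED3 (-1.67), EPHA2 (-1.50) and PHLDA1 (-1.45) fell as well. The MAPK output list fell in 9 of 10 genes (10 adjusted over the list alone; median -0.85; adjusted p = 1.44e-14 in limma's camera, adjusted p = 0.0643 with an estimated correlation). EPHA4 stood at -0.39 (limma adjusted p = 0.0592, and 0.0418 under quantile normalization). The call of ETV4 (-0.16, limma adjusted p = 0.0421) was lost with the replicate block (0.0679) and without DMSO replicate 1, 2 or 3 or TRI-611 replicate 1 or 3 (adjusted p from 0.0702 to 0.150). Medians of the list within batches 1, 2 and 3 were -0.87, -0.86 and -0.86, with all 10 members lower each time.

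The pro-death gene BMF rose in NCI-H2228 from 19.7 ± 0.304 to 67.9 ± 1.66 TPM (SD, n = 3 each; log2 change 1.74, SE 0.0428), and KLHL24 (1.66), the cyclin gene CCNG2 (1.45) and the mitochondrial kinase gene PDK4 (1.25) rose with it. FOXO targets rose in 19 of 27 cases and fell in 1 (21 and 2 adjusted over the list alone; median 0.42; adjusted p = 1.52e-12 in limma's camera, adjusted p = 0.167 with an estimated correlation). MYC and ribosome biogenesis genes fell in 25 of 33 cases and rose in 0 (27 and 0 adjusted over the list alone; median -0.32; adjusted p = 7.43e-18 in limma's camera, adjusted p = 0.127 with an estimated correlation). NF-kB targets and chemokines fell in 10 of 22 cases (11 fell and 1 rose adjusted over the list alone; adjusted p = 1.51e-07 in limma's camera, adjusted p = 0.204 with an estimated correlation), with IL6 at -1.37 and CXCL8 at -1.09. Targets of STAT3 fell in 7 of 17 cases and rose in 1 (10 and 1 adjusted over the list alone; adjusted p = 9.76e-05 in limma's camera, adjusted p = 0.250 with an estimated correlation), among them the cytokine brake SOCS1 (-1.13). Mitochondrially encoded genes had a median of 0.28, with 1 of 35 called higher (1 adjusted over the list alone; adjusted p = 0.000268 in limma's camera, adjusted p = 0.357 with an estimated correlation).

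Over all genes in NCI-H2228, limma called 1882 of 16806, 806 higher and 1076 lower, and 29 and 44 of them changed at least 2-fold. The largest rises and falls named by the rule in this line included short RNA genes, such as MIR3181, SNORA46, MIR6813 and SNORD19. The protein-coding genes given above are therefore not the only large changes, and the counting error of such short genes could not be bounded. Without mitochondrially encoded genes the split was 1162 higher and 908 lower. The count fell to 1236 without DMSO replicate 1, 1179 without DMSO replicate 2, 1152 without TRI-611 replicate 1 and 1235 without TRI-611 replicate 3, and to 1052 with no filter on low TPM. The groups did not overlap for 31.4% of tested genes (chance gives 10%). Of 33 lists 19 were called, 7 upward and 12 downward, 18 of them also with the replicate block, and 0 kept the call with an estimated correlation.

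**Figure D2:**
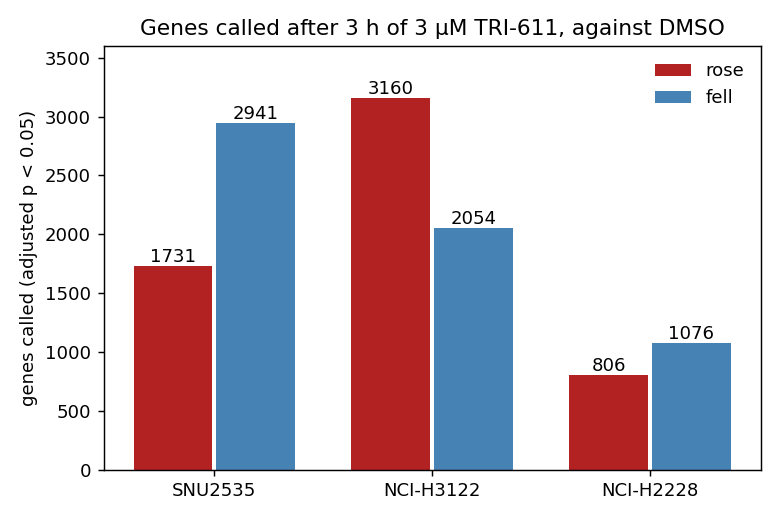
Number of genes called with limma at an adjusted p under 0.05 (vertical axis) in each line, higher (red) and lower (blue) after TRI-611. Calls number 1731 and 2941 in SNU2535, 3160 and 2054 in NCI-H3122, and 806 and 1076 in NCI-H2228, and other scalings move these splits.

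**Figure D3:**
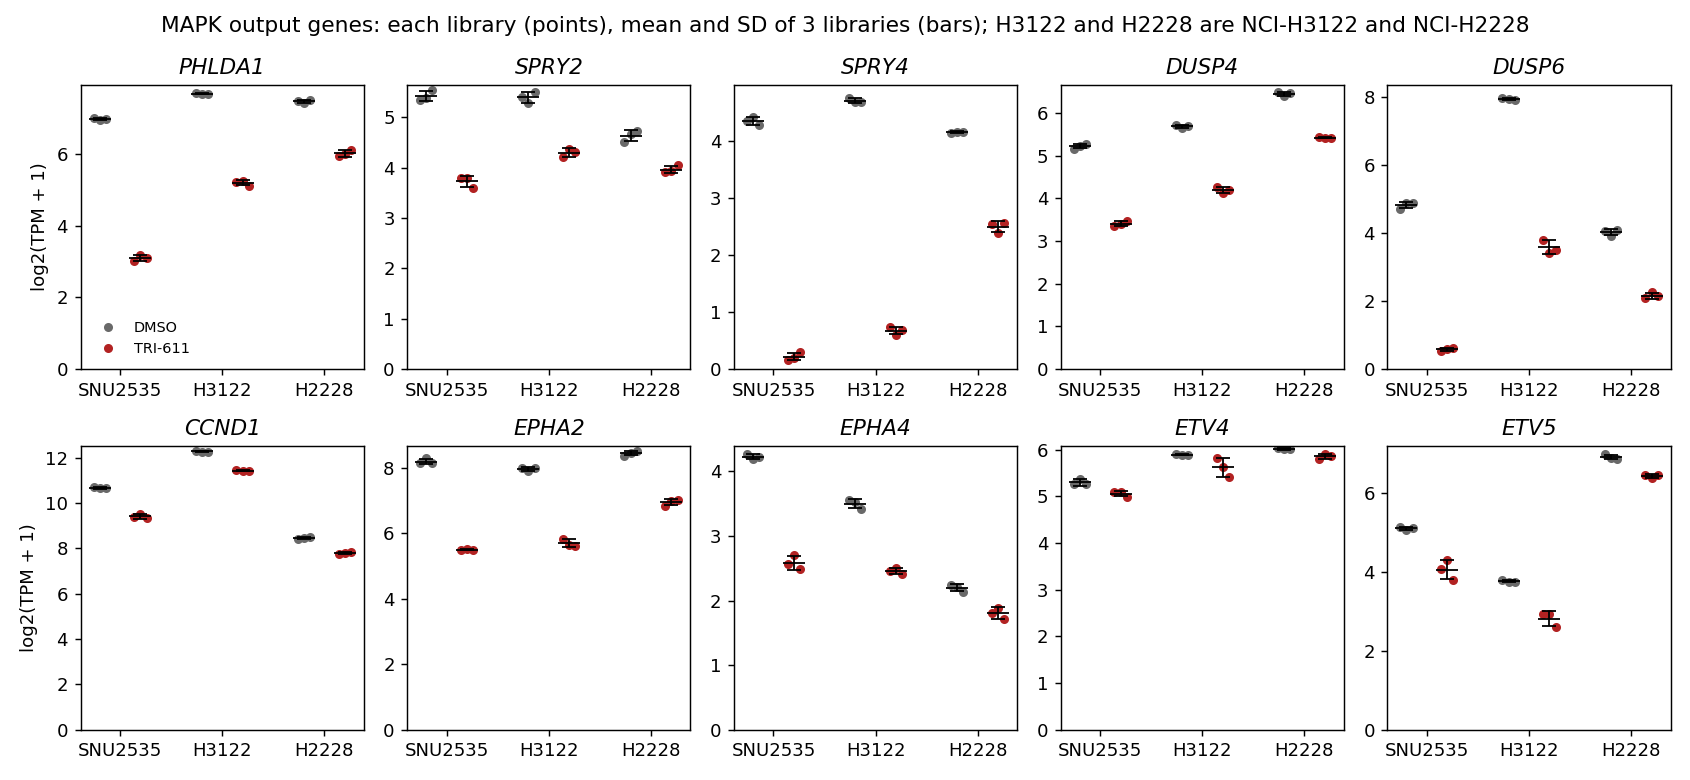
Log2(TPM + 1) of the 10 MAPK output genes in each library (points) by line, with DMSO in grey and TRI-611 in red and the mean and SD of 3 libraries as black bars. The log2 change of DUSP6 is -4.24, -4.36 and -1.86 in SNU2535, NCI-H3122 and NCI-H2228.

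The next comparison asked whether the responses themselves differ between lines. ERK-driven genes fell less in NCI-H2228 than in the other lines. The change of DUSP6 differed by -2.38 (log2) between SNU2535 and NCI-H2228 (limma adjusted p = 9.85e-08) and by -2.50 between NCI-H3122 and NCI-H2228 (limma adjusted p = 6.68e-08). For EGR1 the difference was -2.55 and for DUSP5 -2.51 between NCI-H3122 and NCI-H2228, and for PHLDA1 -2.42 between SNU2535 and NCI-H2228. In a list test of the difference, added after the data were seen, the MAPK output genes fell further in SNU2535 (adjusted p = 7.52e-15 in limma's camera, adjusted p = 0.00675 with an estimated correlation) and in NCI-H3122 (adjusted p = 5.85e-13 in limma's camera, adjusted p = 0.0220 with an estimated correlation) than in NCI-H2228. Between SNU2535 and NCI-H3122, RASD1, a Ras-related gene, changed in opposite directions: it rose from 45.3 ± 3.57 to 83.8 ± 1.79 TPM in SNU2535 and fell from 54.7 ± 3.46 to 9.11 ± 1.60 TPM in NCI-H3122 (SD, n = 3 each; difference in log2 change 3.35, limma adjusted p = 6.04e-08). CITED4, a transcriptional coactivator gene, rose in SNU2535 and fell in NCI-H3122 (difference 2.35). The G2/M genes rose more in NCI-H3122, with 24 of 27 differing from SNU2535 and 22 of 27 from NCI-H2228 (adjusted p = 5.27e-10 and 3.78e-14 in limma's camera, adjusted p = 0.536 and 0.150 with an estimated correlation).

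Limma called a different response for 2769 of 13788 genes between SNU2535 and NCI-H3122, 1547 of 14640 between SNU2535 and NCI-H2228, and 1988 of 13878 between NCI-H3122 and NCI-H2228. Of these, 189, 32 and 50 were called in both lines in opposite directions. Across genes, which are not independent replicates, the log2 changes of the pairs correlated at r = 0.550, 0.477 and 0.476.

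**Figure D4:**
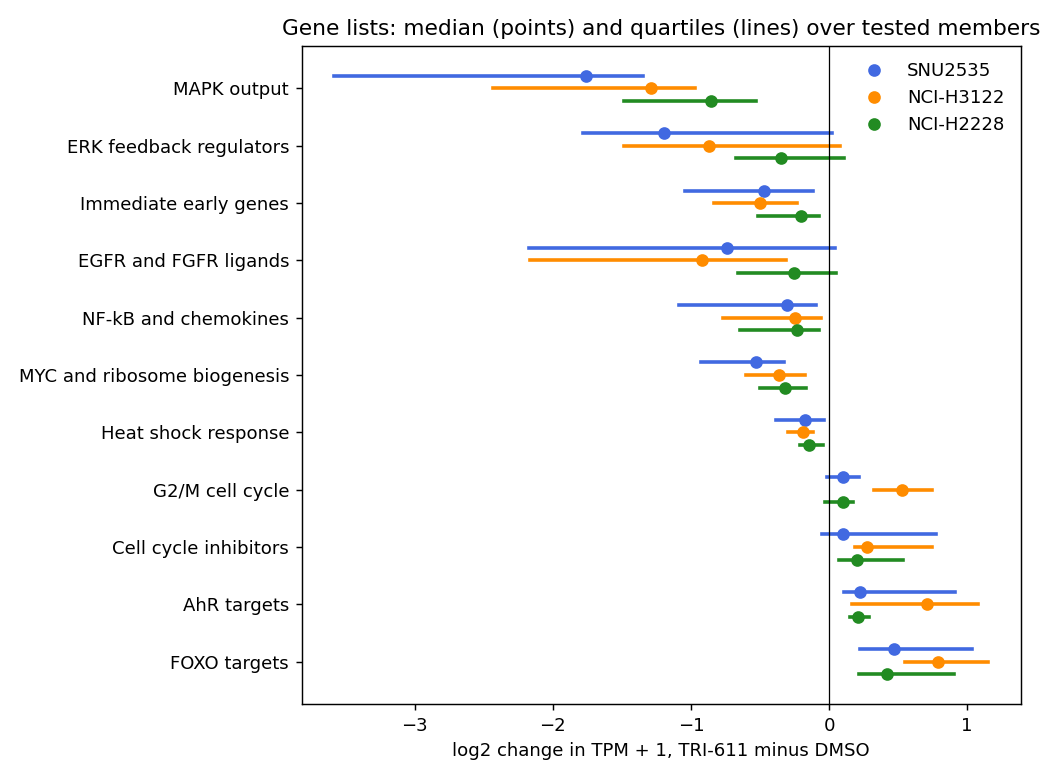
Median (points) and quartiles (lines) of the log2 change in TPM + 1 over the tested members of 11 gene lists in the 3 lines (colours). MAPK output genes have medians of -1.76, -1.29 and -0.85 in SNU2535, NCI-H3122 and NCI-H2228, and FOXO targets 0.47, 0.79 and 0.42.

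Shared calls formed the third comparison. In all 3 lines 338 genes rose and 625 fell, 963 of the 13186 genes tested in all, where independent lists would share 47.1. The largest mean rises belonged to KLHL24 (1.96, 2.47 and 1.66 in SNU2535, NCI-H3122 and NCI-H2228), BMF (1.56, 1.88 and 1.74), CASTOR2 (1.40, 2.04 and 1.39), PIK3IP1, CYP1A1 (1.58, 2.52 and 0.65) and TCP11L2. CYP1A1 started near the floor in SNU2535, with a log2 difference of -5.52 against NCI-H3122 with DMSO. The largest mean falls were those of DUSP6, SPRY4, PHLDA1, FOSL1, EPHA2 and AREG. In each pair of lines and each direction, Fisher's exact test found more shared calls than independent lists would give, with odds ratios from 7.93 to 22.2 and a largest adjusted p of 4.43e-207 (genes are not independent, so these p-values are too small). Falls shared by SNU2535 and NCI-H2228, for example, numbered 822 where 201 would be shared by independent lists. The lines share no DMSO libraries. Leaving out replicate 1, 2 or 3 of every group reduced the 963 shared calls to 415, 392 or 437.

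The DMSO libraries gave the starting levels. ALK was highest in SNU2535, by 0.59 (log2, SE 0.0681, n = 3 each) over NCI-H3122 and by 1.099 over NCI-H2228. DUSP6 was highest in NCI-H3122 at 243 TPM, with a log2 difference of -3.12 for SNU2535 against it and of 3.91 over NCI-H2228, and CYP1A1 was highest there too, 3.96 above NCI-H2228. Limma called 13876, 13675 and 14461 of 18233 genes different between SNU2535 and NCI-H3122, SNU2535 and NCI-H2228, and NCI-H3122 and NCI-H2228. Each line stands for itself only in these contrasts.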

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

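The tests of gene lists for the difference between lines, and all tests of explanations below except those of GC content and length, of chance between dishes and of other splits of the libraries, were chosen only after the result was seen.

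Genes of the G2 and M phases rose more in NCI-H3122 than in the other lines. There the list was also called higher, with medians of 0.10 each (adjusted p = 0.0279 in SNU2535 and 0.0368 in NCI-H2228 in limma's camera, adjusted p = 0.741 and 0.333 with an estimated correlation). The median difference was -0.3931 for SNU2535 against NCI-H3122 and 0.430 for NCI-H3122 against NCI-H2228 (adjusted p = 0.536 and 0.150 in limma's camera with an estimated correlation). Scaling as the source is argued against by a median rise of 0.5685 under quantile normalization. Each gene was set against 50 protein-coding genes matched on GC content, length and TPM, and the median excess was 0.5601, with all 27 above their matched median. The lowest of the 3 batch medians was 0.4114, but the labels do not say that the batches were separate dishes, so a chance difference between dishes, which would then show in every batch, could not be told apart from the treatment. In the test of the difference 24 of 27 genes differed from SNU2535 and 22 from NCI-H2228, which restates the pattern and does not test a cause in this cell line.

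Among genes called the same way in both lines, the change in NCI-H2228 was the smaller one for 75% of 1260 genes shared with SNU2535 and 75.1% of 1223 shared with NCI-H3122. A larger spread there is argued against by its median standard error, at most 1.019 times that of another line. For the 10 MAPK output genes, selection is argued against, as 9 fell less in NCI-H2228 in each pair, and scaling by the gap of 0.4811 in their median under quantile normalization. These 10 do not test selection among other genes. Median differences of SNU2535 and NCI-H3122 against NCI-H2228 were 0.0173 and 0.327 for FOXO targets. They were -0.253 and -0.0199 for MYC and ribosome biogenesis genes, so not every list responded less in NCI-H2228 in each pair. A lower ALK level may play a part, as NCI-H2228 had the lowest ALK value, 11.03 TPM with DMSO, but with 3 lines this could not be told apart from any other difference between them.

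CYP1A1 rose in every line, and AhR targets rose more in NCI-H3122 than in NCI-H2228 by a median of 0.498 (adjusted p = 0.566 in limma's camera with an estimated correlation). With DMSO, CYP1A1 lay near the floor in SNU2535 (log2 difference of -5.52 against NCI-H3122). It passed the filter in SNU2535 only through the TRI-611 libraries. A single library as the source is argued against by the smallest change of CYP1A1 over the 9 same-batch pairs, 0.5955. That value does not bound the counting error of few reads in SNU2535, as the depth is unknown. Scaling is argued against by CYP1B1, another AhR target, whose smallest change over the lines was 0.3029 under quantile normalization. Of the AhR activity expected to raise CYP1A1, CYP1B1, AHRR and TIPARP together, 1 call spoke against it as the whole cause: TIPARP fell in SNU2535 (-0.62). That bound rests on 1 gene in 1 line, and TIPARP may also answer to other signals. An action of the compound apart from ALK stays open, as no other ALK inhibitor was profiled.

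Responses that differed between SNU2535 and NCI-H3122 by the interaction test numbered 2769 genes. RASD1 (3.348), CITED4 (2.353) and DNAJB5 (1.975) changed upward in SNU2535 relative to NCI-H3122. RASSF10 (-2.09), FOXQ1 (-2.056), PHLDA1 (-1.389), SPRY2 (-0.6007), EPHA4 (-0.6004), EPHA2 (-0.418), CCND1 (-0.3973) and DUSP4 (-0.336) changed downward. RNU6-1091P had a fitted difference of -4.44 but was listed at 0 in the TRI-611 libraries of SNU2535. Lists are given where limma's camera passed and at least 0.5 of the members differed: the median differences were -0.3666 for MAPK output genes (adjusted p = 0.536 with an estimated correlation) and 0.1573 for immediate early genes (adjusted p = 0.536 with an estimated correlation).

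Between SNU2535 and NCI-H2228 1547 genes differed by the interaction test. DDIT4L, an inhibitor of mTOR signalling, differed by 1.571. SPRY4 (-2.485), PHLDA1 (-2.422), DUSP6 (-2.384), EPHA4 (-1.252), EPHA2 (-1.195), SPRY2 (-1.021), DUSP4 (-0.7896), CCND1 (-0.5774) and ETV5 (-0.5674) fell further in SNU2535. Calls of 3 genes of low TPM did not hold without most single libraries. SNORA65 (2.383) kept its call without DMSO replicate 3 or TRI-611 replicate 2 of SNU2535 or DMSO replicate 3 or TRI-611 replicate 1 of NCI-H2228, and lost it without any other library (adjusted p from 0.0536 to 0.0694). MRPS36P1 (1.467) kept it without DMSO replicate 1 or TRI-611 replicate 2 of SNU2535 or DMSO replicate 1 or TRI-611 replicate 3 of NCI-H2228, and lost it otherwise (0.0690 to 0.0908). MIR106B (-2.494) kept it without TRI-611 replicate 2 of SNU2535 or DMSO replicate 3 of NCI-H2228, and lost it otherwise (0.0558 to 0.108). Its limma adjusted p reached 0.1098 in an alternative that kept all libraries. List medians differed by -1.108 for MAPK output, -0.8874 for ERK feedback regulators, -0.2284 for immediate early genes, -0.2526 for MYC and ribosome biogenesis genes and -0.4433 for EGFR and FGFR ligands (adjusted p = 0.00675, 0.00675, 0.429, 0.250 and 0.0392 with an estimated correlation).

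Between NCI-H3122 and NCI-H2228 1988 genes differed by the interaction test. ATOH8 differed by 2.052, EGR1 by -2.551, DUSP5 by -2.513, DUSP6 by -2.501, SPRY4 by -2.384, PHLDA1 by -1.033, EPHA2 by -0.7771, EPHA4 by -0.6514, ETV5 by -0.4616, DUSP4 by -0.4536 and SPRY2 by -0.4206. CCND1 differed by -0.1802, a call lost under quantile normalization (adjusted p = 0.297) and without DMSO replicate 1 of NCI-H3122 (0.0532) or of NCI-H2228 (0.0508). Of the short RNA genes, SNORA60 (2.387) lost the call with the replicate block (adjusted p = 0.0549) and without any library (0.0619 to 0.0940) except DMSO replicate 3 or TRI-611 replicate 1 of NCI-H3122 or TRI-611 replicate 2 of NCI-H2228, MIR138-1 (2.175) was listed at 0 in the DMSO libraries of NCI-H3122, and MIR3648-1 differed by -3.785. List medians differed by -0.5565 for MAPK output, -0.4371 for ERK feedback regulators, -0.341 for immediate early genes, 0.3267 for FOXO targets and -0.6011 for EGFR and FGFR ligands (adjusted p = 0.0220, 0.0446, 0.150, 0.609 and 0.0199 with an estimated correlation).

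Libraries split 3 against 3 allow only 10 splits, too few for a share under 0.05. In 1 of the 10 splits, the real one, as many genes were called in SNU2535 (4672, highest other 0), NCI-H3122 (5214, highest other 1) and NCI-H2228 (1882, highest other 0), and likewise for each DMSO contrast between lines (13876, 13675 and 14461, highest others 0, 1 and 0). For lists the counts were 1 of 10 in SNU2535 (17, highest other 9), 2 of 10 in NCI-H3122 (16, highest other 16) and 1 of 10 in NCI-H2228 (19, highest other 7). The other split with 16 lists parted 1 numbered pair of libraries, but libraries of the same number hardly correlated, so that is no reason to set it aside. Other splits called at most 1 gene and still passed lists at the preset correlation. The number of lists therefore does not set the real split apart in NCI-H3122. For shared calls 1 of 100 draws was as large (963, highest other 0). Splits that broke the treatment groups of a line called at most 1 gene, so that outcome was all but fixed beforehand. For the difference between SNU2535 and NCI-H3122 it was 1 of 100 (2769, highest other 2163). No draw there kept the treatment groups in both lines, while the 1 such draw for NCI-H3122 and NCI-H2228 called 5609 genes. Draws that regroup the treatment do not test whether 2 lines respond alike, so nothing is excluded by these shares. These draws test only the spread between these libraries and exclude no difference between dishes. For SNU2535 against NCI-H2228 (5 of 100; 1547, highest other 2605) and NCI-H3122 against NCI-H2228 (7 of 100; 1988, highest other 5609) chance was not excluded by that share. The larger draws kept the treatment groups in at least 1 line, a structure of the samples, and draws that kept them in neither line called at most 3, 1 and 1 genes in the 3 pairs.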

How the results depend on the processing

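The tests on protein-coding genes only, without mitochondrially encoded genes, and of lists under other scalings were chosen only after the result was seen. Over the alternatives that kept all libraries, 3470 values of named genes kept direction and side of the threshold, 258 lost the call, 14 gained it and 3 reversed; for lists 273 kept both and 89 lost the call. For the named differences between lines, 207 values kept both, 6 lost the call, 1 gained it and 3 reversed. The cause was not tested except where stated. With an estimated correlation the lists called numbered 0 in SNU2535, 0 in NCI-H3122 and 0 in NCI-H2228. A minimum log2 change of 1 left 319 genes in SNU2535, 336 in NCI-H3122, 73 in NCI-H2228 and 25 shared by all lines, by construction. In NCI-H2228 1052 genes were called with no filter and 1177 with plain empirical Bayes.

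Without 1 library, the genes called ran from 1152 to 1759 in NCI-H2228, and the lists called from 11 to 17 in SNU2535. Without replicate 1, 2 or 3 of every group, the shared calls ran from 392 to 437 (fewer libraries). With the replicate block 4057, 4294 and 1724 genes were called in SNU2535, NCI-H3122 and NCI-H2228. Values that reversed included EML4 at -0.024513 in NCI-H3122 under median-ratio scaling, and ALK at 0.0047374 and EML4 at 0.0028787 in NCI-H2228 without mitochondrially encoded genes. Without 1 library EML4 in NCI-H2228 ran from -0.043537 to 0.0051748. For SNU2535 minus NCI-H3122, DUSP6 differed by -1.0704 (limma adjusted p = 0.000325) and SPRY4 by -1.051 (limma adjusted p = 0.00501) with a pseudocount of 0.1, both called there and not in the main results. SPRY4 differed by 0.16239 and ETV5 by 0.021412 under quantile normalization, and without 1 library ETV4 ran from -0.074146 to 0.12585 and ETV5 from -0.22813 to 0.022218. The BCL2 family in NCI-H3122 (median -0.1629) had the opposite direction in fry. The depth of the libraries is unknown, so counting error of genes of low TPM could not be bounded.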

Other observations

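The test of the glycolysis list under quantile normalization was chosen only after the result was seen, and the values are given without explanation.

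FOXA2, a factor of airway and gut epithelium, fell in SNU2535 (-1.41), NCI-H3122 (-1.97) and NCI-H2228 (-0.82), while NKX2-1, a lung lineage factor, rose (0.31, 1.05 and 0.75). The lung epithelial list did not pass in any line (adjusted p = 0.425, 0.865 and 0.929 in limma's camera): 6 of 20 members rose and 6 fell in SNU2535, 4 and 4 of 13 in NCI-H3122, and 3 and 3 of 16 in NCI-H2228 (8 and 6, 5 and 4, and 3 and 4 adjusted over the list alone). HK2, which starts glycolysis, fell in the 3 lines (-1.22, -0.72 and -0.67), and 8 of 23 glycolysis genes fell in NCI-H2228 (13 adjusted over the list alone; adjusted p = 5.84e-06 in limma's camera, adjusted p = 0.250 with an estimated correlation). In NCI-H3122 6 of 22 glycolysis genes fell (5 adjusted over the list alone; adjusted p = 0.0216 in limma's camera, adjusted p = 0.798 with an estimated correlation), a call lost under quantile normalization (0.115) and without TRI-611 replicate 2 (0.0501) or 3 (0.0749). In SNU2535 2 of 22 rose and 6 fell (2 and 6 adjusted over the list alone; median 0.01), and the list did not pass (adjusted p = 0.752 in limma's camera).

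Heat shock genes fell in 8 of 15 cases in SNU2535 (10 adjusted over the list alone; adjusted p = 0.00620 in limma's camera, adjusted p = 0.259 with an estimated correlation), among them the chaperone genes DNAJB1 (-0.90) and HSPA8 (-0.49). The list was called lower in the other lines too. In NCI-H3122 10 fell and 3 rose, and in NCI-H2228 6 fell and 2 rose (adjusted p = 0.00516 and 0.00450 in limma's camera, adjusted p = 0.399 and 0.311 with an estimated correlation). Interferon response genes rose in 10 of 31 cases and fell in 1 in SNU2535 (10 and 1 adjusted over the list alone; median 0.02; adjusted p = 0.0184 in limma's camera, adjusted p = 0.322 with an estimated correlation), with IFIT2 at 1.63 and STAT2 at 0.41. The interferon list did not pass in NCI-H3122 or NCI-H2228 (adjusted p = 0.865 and 0.160 in limma's camera). The genes of the ligase and proteasome list, which holds CRBN, did not pass as a list in any line (adjusted p = 0.918, 0.441 and 0.106 in limma's camera).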
